A study of Drosophila melanogaster with 288 samples.

How the data were processed

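Expression was measured in intact adult offspring of a diallel of 9 Drosophila melanogaster lines, a crossing scheme in which each line is mated to each of the other lines in both directions, so that 72 crosses arise. Female and male offspring of each cross were sampled in 2 biological replicates, which gives 144 female and 144 male samples and 144 groups of 2 samples each. Per the labels each replicate pooled flies from separate sub blocks of crosses, and each array held the female and the male sample of 1 cross, with the dyes Cy3 and Cy5 exchanged between the 2 replicates. The labels give crosses 128x23 and 134x128 the same dye orientation in both replicates. Which parent of a cross label was the mother is not given in the sources used here, so the parents are called first-named and second-named.

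Each deposited sample file holds 1 dye channel with a foreground and a background intensity per spot, on a linear scale and not normalized, per the file headers. An array held 22575 features in 105 rows and 215 columns. The deposited series table holds natural log values, and in 286 of its columns these equalled the natural log of the foreground minus the background intensity of the same sample within 0.001. The remaining 2 columns, labelled female and male 128x23 replicate 1, held the values of male 128x17 replicate 2 and female 128x23 replicate 2, and these 2 columns were not used. No gene name stands beside a feature in the files used here, so features are given by their number on the array, control spots could not be told apart from the rest, and the planned comparisons by gene list, by chromosome and among probes of 1 gene were not run.

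The female and male files of a cross and replicate were put together as an array. Spot flags were identical in the 2 files of all 144 arrays and were shared with no other file. Background was corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3, the log ratios were normalized within arrays by loess, and the mean log2 values were normalized between arrays by Aquantile. Spots with a flag other than 0 (0.998% of spots, with the meaning of the flags not given in the sources used here) were left out, and their place in the fit was filled by the missing-plot method with the residual degrees of freedom reduced. No feature was flagged on enough arrays to be removed, so 22575 features were tested, without a floor on signal. The offset pulls log ratios of dim features towards 0, so folds of dim features are understated. Spots of at least 65000 units numbered at most 4 per Cy3 channel and 25 per Cy5 channel. The median foreground of a channel ranged from 55.6 to 156.6 units in Cy3 and from 62.9 to 178.1 in Cy5, and its median ratio to background from 1.89 to 6.12 in Cy3 and from 1.50 to 3.48 in Cy5. The number of arrays limits the precision.

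Sex bias was tested with limma on the female minus male log2 ratio of each array, with terms for dye orientation and for the 72 crosses, so that the array was the block. Differences among crosses were tested within each sex with a dye term, as a moderated F test on 71 degrees of freedom and on its 4 orthogonal parts. General combining ability (GCA, 8 degrees of freedom) is the mean deviation of all crosses of a line, and specific combining ability (SCA, 27) is the deviation of a pair of lines from the sum of their GCA effects. The general reciprocal effect (8) is the mean difference between the crosses in which a line is named first and those in which it is named second, and the remaining reciprocal differences (28) belong to single pairs. The same parts of the sex ratio tested whether cross differences were unequal in the sexes. A call means a Benjamini-Hochberg adjusted p under 0.05 in limma. Variance components were estimated by the method of moments, negative estimates were kept, and shares of the genetic variance were pooled over features with a jackknife error over the 9 lines. GCA effects of the sexes were correlated across lines between different arrays only. The residual between 2 replicates carried 71 degrees of freedom. The fit was tested on simulated data on the real design over 22575 features. For sex bias it recovered 95% of 100 features with a log2 ratio of 0.25 and all 100 with a log2 ratio of 1. In females it recovered 96.5% of 200 features with GCA (SD of line effects 0.2 log2 units) and 95.5% of 200 with SCA (SD of pair effects 0.3). It also recovered 96% of 200 with a general reciprocal effect (SD of line effects 0.2). In the real data the median genetic SD of features with cross differences in females was 0.19. That SD joins all parts and counts the GCA variance 2 times, so it is not on the scale of the simulated SDs. The mean variance components over all features in females were 0.0054 for GCA and 0.0024 for SCA. These lie below the squares of the simulated SDs, and recovery of smaller effects was not simulated. Noise was drawn independently for the 2 channels of an array. Calls among features without any simulated change numbered 13 for sex bias, 16 for GCA, 16 for SCA and 7 for the general reciprocal effect, or 3.62%, 4.41%, 7.69% and 3.52% of calls. A further 151 calls of sex bias and 154 of GCA fell on the 600 features simulated with other random effects, whose means over crosses or over lines were not set to 0.

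Samples kept the groups of their labels throughout. The female minus male ratios of each array were correlated with the mean of the other arrays, and the background of each channel was set against its dye label. By these checks 4 arrays with a sex ratio apart and then 2 arrays with inverted backgrounds were set apart, 6 in all, and each leading count was also computed without the 6, the 4 or the 2, alternatives chosen after the data were seen. The pairing of samples on arrays comes from the series design. With dye removed, the difference between replicates 1 and 2 in females correlated with that in males at a median of 0.40 over the 72 crosses, above 0.1 in 65 of them. Named features were chosen by a rule fixed before the data were examined, as those with the largest sex ratio among features changed in 1 direction on at least 95% of arrays, and those with the largest GCA component in each sex. Because features could not be named, only the first of these are printed. Alternatives were per-channel median centring, quantile normalization of all channels, no background correction, the series table, features in the upper part of the signal range, no dye term, leaving out the 2 crosses without a dye exchange, the replicate number as a term, leaving out each replicate and each line, lines as random effects, other summaries of the variance shares, a threshold of 1.5-fold, and sexes as independent samples. Figures were drawn with matplotlib 3.10.9.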

Results

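Whole adult flies from a diallel of 9 Drosophila melanogaster lines (17, 23, 58, 75, 83, 89, 128, 134 and 145) were profiled on 2-colour arrays to ask how expression differs between the sexes and how those differences are inherited. The 72 crosses, counting both directions of each pair of lines, were each represented by 2 arrays, and each array compared female with male offspring of the same cross. Sex held 50.9% of the variance of normalized log2 values, more than any other term fitted, while dye held 27.98%, cross 6.66% and replicate number 0.282%. Though its share was small, an effect of the replicate number was called for 2405 features in females and 1939 in males. The first principal component (56.2% of the variance) followed sex (absolute r = 0.95) and the second (30.0%) followed dye (absolute r = 0.96). The 2 replicates of a group correlated at a median of 0.89 in females and 0.88 in males, with the lowest values at 0.70 and 0.67.

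The sexes were separated on 140 arrays in the direction of their labels, with correlations of 0.66 to 0.90 between an array's female minus male ratios and the mean of the other arrays (median 0.79). The other 4 arrays stood apart. The array labelled 58x83 replicate 1 correlated at -0.80 and that labelled 128x89 replicate 1 at -0.75, while those labelled 134x75 replicate 1 and 134x128 replicate 1 correlated at -0.17 and 0.0051. On a score that is 0 for the mean male channel and 1 for the mean female channel over 3987 features with sex bias of at least 2-fold, the other channels labelled female ranged from 0.78 to 1.17 and those labelled male from -0.15 to 0.19. The channel labelled female 58x83 replicate 1 scored -0.088 and its male partner 0.98, and the channel labelled female 128x89 replicate 1 scored 0.14 and its male partner 1.01. The channels labelled female and male 134x75 replicate 1 scored 0.59 and 0.68, and those of 134x128 replicate 1 scored 0.66 and 0.70. On 142 arrays the channel labelled Cy5 had the higher background. On 2 further arrays, labelled 128x89 replicate 2 and 134x145 replicate 1, the channel labelled Cy3 had the higher background (58.5 against 19.1 units and 59.8 against 26.6 units). Their differences between dyes ran against the labels as well, with correlations of -0.95 and -0.82 to the mean dye effect, against 0.58 or more on the other arrays, and the dye term followed the labels on these arrays too. These 6 arrays were kept in all comparisons, and counts without them (138 arrays) stand beside those over all arrays. Both arrays of cross 128x89 are among the 6, so counts without the 6 leave that cross out. Crosses 58x83, 134x75, 134x128 and 134x145 then have no second replicate. Without only the 4 arrays with a sex ratio apart, 128x89 keeps only its array with an inverted background. Without only the 2 arrays with inverted backgrounds, it keeps only its array with a sex ratio apart.

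**Figure D1:**
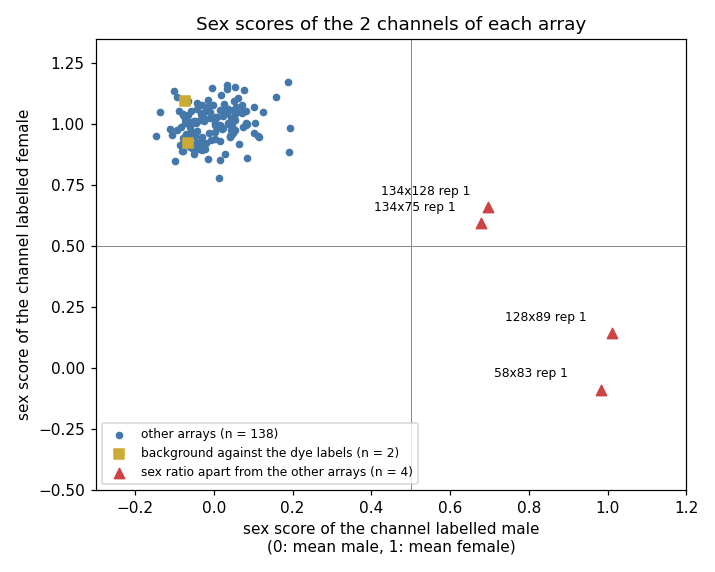
Sex score of the channel labelled female (vertical axis) against that of the channel labelled male (horizontal axis) for each array, without units, where 0 is the mean male and 1 the mean female channel. Triangles mark the 4 arrays whose sex ratio stood apart from the others, squares the 2 arrays whose background went against the dye labels, and the female channels of the remaining 138 arrays lie between 0.78 and 1.17.

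Most features differed between the sexes. Of 22575 features, 8899 were higher in females and 9354 were higher in males (39.4% and 41.4%), and 4322 were not called. Without the 6 arrays the counts were 8911 and 9832, and 8807 and 9303 features were called in the same direction both ways. Most differences were small, with a median absolute log2 ratio of 0.22. A difference of at least 2-fold was found for 1501 features higher in females and 2274 higher in males, which were 1609 and 2378 without the 6 arrays. Large differences were mostly towards males. At least 4-fold differences numbered 235 in females and 978 in males, at least 8-fold differences 36 and 475, and at least 16-fold differences 8 and 147. The balance of the 2-fold counts depended on scaling, since per-channel median centring gave 2612 features higher in females and 1700 higher in males, and quantile normalization of all channels gave 2160 and 1963. With median centring 67.6% of all calls were higher in females, against 48.8% with loess. At 8-fold the counts were higher in males under each normalization tried, with 71 against 317 under median centring and 61 against 376 under quantile normalization.

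The strongest female-biased feature, feature 7868 in row 37 and column 128 of the array, had a mean log2 signal of 13.46 ± 0.70 (SD over all female samples) in females and 8.69 ± 1.00 (SD over all male samples) in males. Its log2 ratio was 4.76 ± 0.13 (SE), 27.1-fold, with the female higher on 140 arrays and lower on 4 (adjusted p = 5.42e-48). Feature 12653 followed with a log2 ratio of 4.45 ± 0.12 (SE), higher in the female on 138 of 141 arrays (adjusted p = 1.58e-47). The strongest male-biased feature, feature 6866 in row 32 and column 201, had a mean log2 signal of 13.21 ± 0.87 (SD over all male samples) in males and 6.73 ± 1.11 (SD over all female samples) in females. Its log2 ratio was -6.49 ± 0.15 (SE), 89.8-fold higher in males, on 141 arrays against 3 (adjusted p = 4.33e-51). Feature 13606 was 81.4-fold higher in males, also on 141 arrays against 3 (adjusted p = 8.64e-51). When the 6 arrays were left out the log2 ratios of features 7868 and 6866 were 4.99 ± 0.053 (SE) and -6.77 ± 0.044 (SE).

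**Figure D2:**
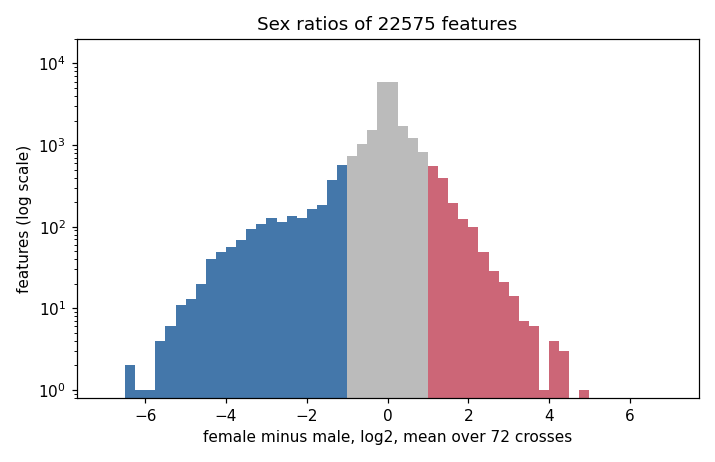
Number of features (vertical axis, log scale) by female minus male log2 ratio averaged over 72 crosses (horizontal axis, bins of 0.25) over all arrays. Bars beyond 1 are features at least 2-fold higher in females and bars beyond -1 those at least 2-fold higher in males, where 475 features lie at 8-fold or more against 36 in females.

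Expression also differed among the 72 crosses within each sex, beyond the spread of the 2 replicates. Females had 3228 such features (14.3%) and males 3170 (14.0%), and without the 6 arrays 3194 and 4054. Per-channel median centring gave 2394 and 1509. Without only the 4 arrays with a sex ratio apart the counts were 3744 and 4840, and without only the 2 with inverted backgrounds 4743 and 5503. The genetic standard deviation of the features called over all arrays had a median of 0.19 log2 units in females and 0.20 in males. Their median residual standard deviations were 0.21 and 0.22. The median absolute sex ratio over all features was 0.22 log2 units, so typical cross and sex differences were of like size. Both sexes called 1536 features, where independent lists of these sizes would share 453.3, although both sexes of a cross lay on the same arrays and part of the excess may come from shared spots. Without line 128 the female count was 1673, without line 23 it was 1712, and without line 17 it was 2117.

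The parts of the diallel were far from equal in the number of features called. An effect of a line rests on more arrays than an effect of a pair, and its test on fewer degrees of freedom. The tests thus differ in power, and the counts do not measure the relative size of the parts. GCA, the mean effect of a line over all its crosses, was called for 7053 features in females and 6192 in males (31.2% and 27.4%), and for 7495 and 8104 without the 6 arrays. SCA was called for 112 features in females and 184 in males (156 and 220 without the 6 arrays). The general reciprocal effect, a difference between a line as first-named and as second-named parent, was called for 700 features in males and 23 in females (773 and 34 without the 6 arrays). Remaining reciprocal differences were called for 39 features in females and 61 in males (34 and 45 without the 6 arrays). Lines were treated as fixed in these tests, and with lines as random effects 4923 features in females and 5233 in males had GCA, while 379 in males and 9 in females had a general reciprocal effect. Leaving out only the 4 arrays with a sex ratio apart gave 819 features with SCA and 1462 with a general reciprocal effect in males, and 253 and 59 with remaining reciprocal differences in females and males. Leaving out only the 2 arrays with inverted backgrounds gave 793 and 1574 for SCA and the general reciprocal effect in males, 714 and 138 in females, and 675 and 1158 for remaining reciprocal differences in females and males. SCA and general reciprocal counts in both sexes changed by more than 1.5 times under several settings, and without line 23 the GCA count in females was 4327. Leaving out each line or replicate gave GCA counts down to 2125 in females and 2525 in males, and general reciprocal counts down to 150 in males.

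**Figure D3:**
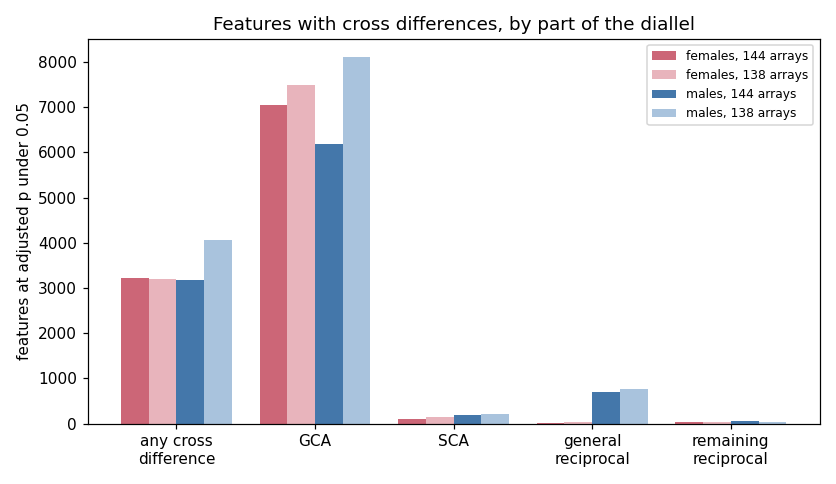
Number of features at adjusted p under 0.05 (vertical axis) with any difference among crosses and with each part of the diallel (horizontal axis), in females and males, over all arrays and over the 138 arrays left without the 6 arrays. GCA has the tallest bars in each sex, with 7053 features in females and 6192 in males over all arrays.

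At the 700 features with a general reciprocal effect in males, GCA and general reciprocal effects were correlated over the 9 lines, with a median of 0.69 across features and 65.9% of features above 0.5. Over all 22575 features the median was 0.086 in males and 0.0040 in females. In 100 permutations of the lines the median over the 700 features lay between -0.20 and 0.25. Without the 6 arrays the median was 0.70 over 773 features, without only the 4 arrays with a sex ratio apart it was 0.40 over 1462 features, and without only the 2 arrays with inverted backgrounds 0.35 over 1574 features.

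**Figure D4:**
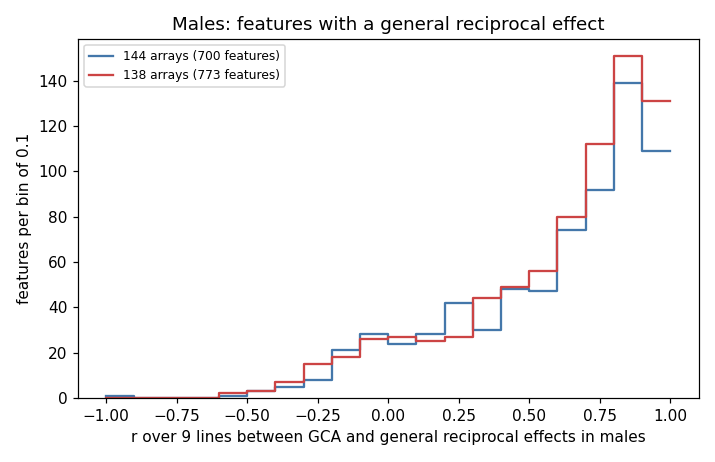
Number of features per bin of 0.1 (vertical axis) by the correlation over 9 lines between GCA and general reciprocal effects in males (horizontal axis), for the 700 features called over all arrays and the 773 called over 138 arrays. Most features lie at high positive values, with a median of 0.69 over all arrays.

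Single features showed how a line acted. The feature with the largest GCA component in females, feature 2933, was lower in crosses of line 128 by a GCA effect of -3.83 ± 0.099 (SE) log2 units in females and -2.10 ± 0.078 (SE) in males. Its effect in crosses of line 134 was 0.94 ± 0.099 (SE) in females and 0.39 ± 0.078 (SE) in males. Its GCA passed the test in both sexes (adjusted p = 2.88e-43 in females and 1.24e-33 in males), and its GCA differed between the sexes (adjusted p = 5.58e-27 for the sex ratio). The feature with the largest GCA component in males, feature 1115, was higher in males of crosses of line 17 by 2.29 ± 0.050 (SE) log2 units, with 0.042 ± 0.072 (SE) in females. Its GCA was called in males (adjusted p = 1.00e-47) and not in females (adjusted p = 0.591), and the difference between the sexes was called as well (adjusted p = 9.60e-33).

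Lines differed in the number of features they moved. In females, crosses of line 23 deviated for 4566 features, those of line 17 for 2617 and those of line 58 for 2350, while line 83 deviated for 673. In males, line 17 deviated for 2278 features, line 128 for 2047 and line 23 for 1898, and line 83 for 945. With the 6 arrays left out, line 23 deviated for 4126 features in females and 2652 in males, and line 17 for 3910 and 3145.

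**Figure D5:**
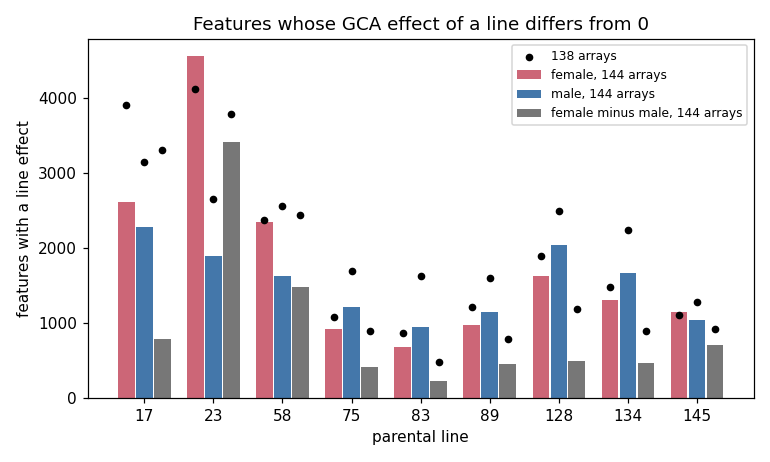
Number of features with a GCA effect different from 0 (vertical axis) for each of the 9 lines (horizontal axis) in females, in males and for the female minus male ratio. Bars are counts over all arrays and black points counts over 138 arrays, and line 23 has the tallest female bar with 4566 features.

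Pooled over features, GCA held 68.4% ± 32.0 (SE over 9 lines) of the genetic variance in females and 81.3% ± 17.5 in males. The female minus male difference was -12.9 ± 44.0 percentage points, well within its error. SCA held 14.9% ± 15.02 in females and 2.99% ± 14.6 in males. The general reciprocal effect held -0.602% ± 6.40 in females and 15.8% ± 6.25 in males, a difference of -16.4 ± 10.1 points. Remaining reciprocal differences held 17.3% ± 19.4 and -0.0519% ± 10.01. Without the 6 arrays GCA held 82.2% ± 10.5 in females and 76.7% ± 10.4 in males, and the difference was 5.51 ± 13.0 points. The shares depended on the dye term, without which the GCA share was -12.9% in females and -12.6% in males, and on the arrays left out. Without only the 4 arrays with a sex ratio apart GCA held 62.0% in females and 55.0% in males, where SCA held 21.7%, the general reciprocal effect 11.9% and remaining reciprocal differences 11.4%. Without only the 2 arrays with inverted backgrounds GCA held 50.5% in females and 45.3% in males, where the other shares were 22.6%, 6.94% and 25.2%. No part of the genetic variance differed between the sexes by more than 2 SE over all arrays or without the 6 arrays. The genetic variance was 19.8% of the sum of genetic and residual variance in females and 15.7% in males, and 23.0% and 24.9% without the 6 arrays.

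The size of the sex difference itself varied among crosses. The female minus male ratio differed among the 72 crosses for 1109 features over all arrays. Without the 6 arrays, and so without cross 128x89, it differed for 2249 features, and 997 features were called both ways. Of the 1109 features, 117 had sex bias of at least 2-fold and 83 had no call of sex bias, and of the 2249 features 729 and 75. By parts of the diallel, GCA of the sex ratio was called for 4750 features (7122 without the 6 arrays), SCA for 35 (59), the general reciprocal effect for 401 (593) and remaining reciprocal differences for 19 (12). Without only the 4 arrays with a sex ratio apart 2727 features differed among crosses, SCA was called for 369, the general reciprocal effect for 1003 and remaining reciprocal differences for 234, and without only the 2 arrays with inverted backgrounds these counts were 4649, 952, 568 and 2340. GCA of the sex ratio and its general reciprocal effect were called for fewer features under per-channel median centring (1959 and 161), without replicate 2 (835 and 110) and without line 23 (2052 and 244), and the general reciprocal effect for 236 without replicate 1. Crosses of line 23 deviated in sex ratio for 3412 features, those of line 58 for 1478 and those of line 17 for 780, and line 17 had 3305 without the 6 arrays. Without line 23 the count over crosses was 507, without line 145 it was 681 and without line 128 it was 696.

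Line effects were positively correlated between the sexes at features with GCA in both. For these 4039 features, the median correlation over the 9 lines between female and male GCA effects, taken from different arrays, was 0.61 (quartiles 0.43 and 0.75), and 96.4% of features had a correlation above 0. In 100 permutations of the line labels the highest median was 0.28. Within a sex, the 2 replicates gave a median correlation of 0.77. Corrected for the noise of single replicates, the pooled correlation between the sexes was 0.75 ± 0.059 (SE over 9 lines), and without the 6 arrays it was 0.73 ± 0.019 over 5054 features. These features were chosen for GCA in both sexes. For the 3014 features with GCA in females only the median correlation was 0.29 and the pooled one 0.66 ± 0.55, and for the 2153 with GCA in males only 0.28 and 0.42 ± 0.17. Over all 22575 features the pooled correlation was 0.71 ± 0.20, and 0.64 ± 0.036 without the 6 arrays.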

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

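The groupings without the 6 arrays set apart, the comparison of male and female counts without those arrays, and the correlations without the 6 arrays or without only 4 of them were tests chosen after the results were seen. Tests of the difference between the sexes found 1109 features whose sex ratio differed among the 72 crosses. GCA differed between the sexes for 4750 features, SCA for 35, the general reciprocal effect for 401 and the remaining reciprocal differences for 19. Over the alternatives run these counts ranged from 507 to 4649 for crosses, 835 to 7166 for GCA, 2 to 952 for SCA, 110 to 1003 for the general reciprocal effect and 0 to 2340 for the remaining reciprocal differences. The count of 0 came from limma with spots kept despite a flag, where 1048 features had an unadjusted p under 0.05. Each group held 2 samples, so no search for single samples far from the rest of their group was made.

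Counts were set against 100 groupings each, the real one included. Exchanging the sexes at random on the arrays gave at most 12317 features with sex bias, against 18253 with the labels. With crosses given at random to arrays, the highest other count of features differing among crosses was 693 against 3228 in females and 2799 against 3170 in males. The highest other counts for GCA were 1292 against 7053 in females and 347 against 6192 in males, and for the general reciprocal effect in males 309 against 700. For each of these results only the real grouping, 1 of 100, was as large, the smallest share that 100 groupings can give. Giving crosses to arrays at random removes all cross differences at once. The GCA and general reciprocal counts were thus set against no cross differences of any kind, and not each against the other parts. For the sex ratio over all arrays 3 of the 100 groupings were as large, which passes the 5% level, but other groupings reached 1344 and 2581 features against the real 1109, so this count alone is weak evidence. Such counts, like the 2799 in males, point to a structure of the arrays beyond the crosses. Without the 6 arrays the highest other counts were 189 against 2249 for the sex ratio and 517 against 4054 for crosses in males. Each had 1 of 100 as large, again the smallest share possible.

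More features had a general reciprocal effect in males (700) than in females (23), and the difference between the sexes passed its own test for 401 features (161 under median centring and 110 without replicate 2). Of the 700 features, 326 passed that test over all arrays. The values argue against the 6 arrays as the source, since without them the male count was 22.7 times the female count. The slope of female on male effects at the 700 features was 0.15 ± 0.026 (SE over 9 lines) between different arrays. This argues against an equal effect of a parent on offspring of both sexes. However, the features were chosen by their male effects, which lowers the slope even under an equal effect, by an amount not estimated. A candidate explanation is that male offspring follow 1 parent, as for genes on the X or Y chromosome, because GCA and general reciprocal effects correlated over lines at a median of 0.69 in males, and at 0.70 without the 6 arrays. The correlation and the slope depended on the arrays. Without only the 4 arrays with a sex ratio apart the correlation was 0.40 and the slope 0.0069 ± 0.42, which decide neither way. Without only the 2 arrays with inverted backgrounds the correlation was 0.35 and the slope 0.21 ± 0.070. In each of these 2 settings cross 128x89 rested on a single array that was itself set apart. A positive correlation is the sign that inheritance from the first-named parent would give, 9.57% of the 700 features had one below 0, and whether that parent was the mother and where these features lie in the genome stay open.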

How the results depend on the processing

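The settings that leave out the 6, the 4 or the 2 doubtful arrays, or keep spots with a flag, and the correlation between the sexes over other sets of features were chosen after the data were seen, and the others before the data were examined. Of 344 alternative values of 15 main results, 279 stayed within 1.5 times of a count or 1 SE of a share or correlation. The SE was computed from the values with each line left out. Those same values were among the alternatives, so for shares and the correlation they stay near 1 SE almost by construction. The female minus male GCA share stayed within 1 SE (44.0 points) under each alternative run, from -31.9 to 19.4 points. That range holds both signs, so it does not show a stable difference. The median Cy5 spot stood 2.13 times above background, and dim signal was tested only by leaving out features in the lower part of the signal range. Unless said otherwise the cause was not tested.

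With per-channel median centring 13824 features were higher in females, 4631 had GCA, 14 SCA and 10 a general reciprocal effect in females, 1509 differed among crosses, 47 had SCA and 338 a general reciprocal effect in males, and the pooled correlation between the sexes was 0.81. SCA in males fell to 85 features with the series table. Among features in the upper part of the signal range, with fewer features tested, 6097 were higher in males, SCA was called for 57 in females and 91 in males, and the general reciprocal effect for 10 in females. Without a dye term, which leaves dye in the residual, 82 features had SCA in males and 621 differed among crosses in sex ratio. Pooled shares then turned negative for GCA, -12.9% in females and -12.6% in males, and for the general reciprocal effect in males, -2.22%.

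Without the 6 arrays 2249 features differed among crosses in sex ratio. Without only the 4 arrays with a sex ratio apart 2727 did, and in males 4840 differed among crosses, 819 had SCA, 1462 a general reciprocal effect and the GCA share was 55.0%. Without only the 2 arrays with inverted backgrounds the sex ratio count was 4649, with 714 for SCA and 138 for the general reciprocal effect in females, and in males 5503 for crosses, 793 for SCA, 1574 for the general reciprocal effect and a GCA share of 45.3%. Removing either kind of array alone thus moved several counts further than removing both. Either setting left cross 128x89 with a single array that was itself set apart. A fault of that array cannot be told from an effect of the cross there. With spots kept despite a flag, SCA was called for 23 features in females and 59 in males, and the general reciprocal effect for 9 in females. With lines as random effects 9 and 379 features had a general reciprocal effect in females and males. The pooled correlation between the sexes was 0.67 over features with GCA in either sex. With negative components set to 0 the GCA share in males was 58.5%, and as a median over features with cross differences the general reciprocal share in males was 2.92%.

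Leaving out each line or replicate gave 1673 to 4054 features differing among crosses in females and 507 to 1094 in sex ratio, 2125 to 7221 with GCA in females and 2525 to 5644 in males, 48 to 100 with SCA in females and 71 to 181 in males, and 4 to 79 with a general reciprocal effect in females and 150 to 664 in males. With the replicate number as a block the counts were 3832 in females, 3709 in males and 1139 for the sex ratio, and with the sexes unpaired 8396 and 8991 features were higher in females and males, and the block moved no count by over 1.5 times. Without 1 replicate SCA and overall cross tests give no value. An unfiltered run was the same as the fit reported, because the filter removed no feature. Genes in place of probes, slide or scan date, and the alternatives for gene lists, X linkage and probes of 1 gene were not run.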

Other observations

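The comparison of GCA among classes of sex bias, the test that 2 arrays hold a mixture, the tests of exchanged channels and of exchanged dye labels, the range test for 1 sex, and the test of less male-biased RNA in line 23 were chosen after the results were seen. The share of features with GCA was compared between features with sex bias and other features of like mean signal over both sexes, without a test of the difference. A feature higher in males was thus dimmer in females and brighter in males than its matched others, and the reverse for features higher in females. These shares therefore do not separate sex bias from signal in the sex tested. The residual SD of the biased classes was higher (medians of 0.32 and 0.35 against 0.16 in females, and 0.32 and 0.43 against 0.17 in males), where the others are all features without 2-fold bias. Without the 6 arrays these medians were 0.25 and 0.26 against 0.15 in females, and 0.21 and 0.29 against 0.16 in males. The residual of the biased classes thus fell further than that of the others, so the shares of the 2 settings were tested against unlike residuals. In females, 34.0% of the features at least 2-fold higher in males had GCA, against 53.2% of others matched on that mean signal. Without the 6 arrays the shares were 42.2% against 53.6%, a difference of -11.1 to -4.77 points when each line was left out too. In males, 18.4% of the features at least 2-fold higher in females had GCA against 49.2%. Without the 6 arrays the shares were 45.7% against 57.4%, a difference of -18.4 to -9.05 points when each line was left out too. For features biased towards the sex in which GCA was measured the direction turned with the arrays. Male-biased features in males differed from others by -9.56 points over all arrays and by 17.4 points without the 6 arrays, with 11.2 to 20.7 when each line was left out. Female-biased features in females stood at -10.2 points over all arrays and 6.26 without the 6 arrays, with -3.29 to 6.71 when each line was left out.

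On 4 arrays the female minus male ratios did not follow the other arrays, and no biological explanation was tested, since the labels give none for single arrays. Weak hybridisation of all 4 is argued against by 0 of the 4 arrays with a channel under the 5th percentile of signal over background, although the channel labelled female 128x89 replicate 1 had the lowest median Cy3 foreground (55.6 units), and exchanged dye labels by 0 of the 4 with the lower background in the channel labelled Cy5. For the arrays labelled 58x83 and 128x89 replicate 1 an exchange of the female and male channels stays open, and that 4 of 4 channels lay past the midpoint towards the other sex follows largely from how these arrays were singled out. The channels labelled female (-0.088 and 0.14) scored inside the range of the other male channels (-0.15 to 0.19). Those labelled male (0.98 and 1.01) scored inside the female range (0.78 to 1.17). An exchange would give such scores, and the rule that singled out the arrays did not require them. For the arrays labelled 134x75 and 134x128 replicate 1, 2 of 2 had both channels on the female side of the midpoint, as flies of 1 sex would give in the test set beforehand, but that test cannot tell 1 sex from a mixture. Of their 4 channels 0 lay inside the range of either sex and 4 lay between the ranges, so a mixture of female and male RNA stays open and 1 sex alone is argued against.

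Over all arrays, crosses of line 23 had more GCA effects in females (4566 features) than those of any other line, with 2617 for line 17. Without the 6 arrays the lead was small, with 4126 features for line 23 and 3910 for line 17. Lines 17 and 23 alone had no cross among the 6 arrays, so those arrays move their effects only through terms shared with the other lines. Their counts depend on the residual variance as well. The median residual SD over all features in females was 0.18 over all arrays and 0.17 without the 6 arrays. The dye is argued against, since 46.9% of the arrays of line 23 held the female in Cy5. Among features at least 2-fold higher in females, 94.3% of the line 23 effects in females were positive (398 against 24), and 86.0% without the 6 arrays, as a difference in the make-up of the body may give. Effects of opposite sign in the 2 classes of sex bias were not particular to line 23. Without the 6 arrays the median line 23 effect in females was 0.059 at female-biased and -0.10 at male-biased features. For line 17 these medians were -0.078 and 0.048, and only lines 75 and 128 had medians of the same sign in both classes. Most line 23 effects lay at features with less than 2-fold bias, where 1856 were positive and 1495 negative over all arrays. Less male-biased RNA in these female samples, through mixing of sexes or of channels elsewhere, is also possible, since at features at least 8-fold higher in males the median line 23 effect in females was -0.22 (-0.13 without the 6 arrays). Both explanations stay open for the sex-biased features, because each needs these effects.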
